A study of Homo sapiens with 384 samples.

How the data were processed

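Single cells of MCF7, an established human breast cancer cell line that carries the oestrogen receptor, were profiled with Smart-seq2, a plate-based protocol that makes full-length complementary DNA from the polyadenylated RNA of 1 cell per well. Each GEO sample was 1 well. Per the labels, 192 wells held normoxic cells (the label "Norm" was read as normoxia), 191 held hypoxic cells and 1 well was a blank. The labels gave no oxygen level and no time in hypoxia. They placed the wells on 4 lanes that each held both conditions, with normoxic wells in the lower-numbered plate columns and hypoxic wells in the higher-numbered ones.

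The authors deposited 1 table of raw counts, whole numbers of reads per gene and well, not scaled. Per the submitters' processing notes, HISAT2 2.1.0 and the genome build hg19 were used. The read counter, the annotation and any filter were not given in the sources used here. The table held 20167 gene rows by Ensembl identifier and 92 rows of ERCC spike-ins, synthetic RNAs added to each well. A symbol was found for 19299 rows in a GENCODE v29 name table. The other 868 rows carried 0.376% of the gene reads of the kept cells and were kept under their identifiers. The reference available was of another build, so no coordinates were used. Of the gene rows, 18860 were protein coding in that annotation. Smart-seq2 reads carry no molecular identifiers and no strand, so copies of 1 molecule were counted more than once and antisense partners were not told apart.

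Every column of the table was matched to 1 sample by its title. A well was kept with 50000 or more reads in genes, 2000 or more genes with a read and at most 30% of its reads in mitochondrial-encoded genes. This kept 349 of the 383 cell wells, 177 normoxic and 172 hypoxic. The blank well held 144 gene reads over 108 genes. No doublet caller was run, since the protocol places 1 cell in each well.

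The labels named no culture or replicate, so each condition counted as 1 sample and cells were not treated as replicates. No p-value, standard error or number of changed genes was made from cells. Counts were summed over the kept cells of each condition (165453520 gene reads in normoxia and 169949079 in hypoxia) and scaled to CPM, the part of the gene total without spike-ins that a gene took. The ratio of hypoxia over normoxia was given on the log2 scale with an exact conditional binomial 95% interval for 2 Poisson counts. A share of cells was given with an exact Clopper-Pearson 95% interval. All intervals cover counting error only. Those of ratios take each read as independent, so copies of 1 molecule make them too narrow. A sum of 0 was replaced by a floor of 3 counts within a lane or condition. Ratios were also computed within each lane, and the SD over the 4 lanes, a technical division, served as the spread against which alternatives were judged.

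A gene was called measured at a pooled CPM of 10 or more in at least 1 condition and reads in 10% or more of the cells of at least 1 condition, which held for 9127 genes. For each gene list, the median log2 ratio of the measured members was set beside the medians of 10000 random lists of equal size matched on mean expression, as a description of these libraries. A member counted as higher or lower at a 1.5-fold ratio or more. These counts were repeated with each scaling. Shares of cells and list scores (percent of a cell's reads in the genes of a list) were computed after each cell was thinned without replacement to 50000 reads. The 177 and 172 kept cells all reached that depth. Variable genes were ranked within each condition by the variance to mean ratio of thinned counts over a running median of genes of like mean. Cells of each condition were clustered apart on log counts per 100000 with 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at resolution 1.0. A cluster took a name only with 3 or more markers of that name among its 50 leading genes and at least 1 among its top 10.

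The gene lists, the markers, the filters, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 15 largest and 15 smallest ratios among genes with a pooled CPM of 20 or more and reads in 20% or more of the cells of the higher condition and 1 direction in all lanes and with equal weight per cell. It added up to 4 members of each list with the largest ratios and 1 direction in all lanes, 14 genes fixed by name, the 10 genes with the largest difference in the share of cells and the 10 most variable genes of each condition. A few list members outside the rule were named after their values were seen, and the text says so. The alternatives were equal weight per cell, TMM and median-of-ratios scaling, totals without mitochondrial-encoded genes or without the top 50 genes, no cell filter and a strict one (100000 reads, 4000 genes, 20% mitochondrial), the exclusion of very deep wells, each lane left out, no gene filter and a strict one (CPM of 50, 25% of cells), thinned counts, other thinning seeds and read minimums, and other cluster settings. Scaling to spike-ins, by pooled sums or by the median over cells of gene reads per spike-in read, was added after the data had been examined.

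The functions were tested on simulated sums of the 9127 measured genes with the real totals. In 4 sets of 50 genes set to folds of 1.5, 2, 4 and 0.25, the intervals held the true fold for 94%, 96%, 96% and 96% of the genes. The sums were drawn from the Poisson model that the interval assumes. This checks the code and says nothing about coverage in the real reads. Of 200 lists of unchanged genes, 3% lay outside percentiles 2.5 to 97.5. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for the scaling factors alone.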

Results

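The data were read counts of 384 wells, single MCF7 cells kept in normoxia or in hypoxia and 1 blank well. Each of 4 lanes held 48 normoxic and 48 hypoxic wells, except lane 4 with 47 hypoxic wells. The cell filter left out 34 of these wells. Among them 6 had over 95% spike-in reads, as the blank had, and 14 had under 1000 gene reads. The series asks how single breast cancer cells differ under low oxygen and whether they form sub-populations. After the cell filter 349 cells remained, with 39, 47, 45 and 46 normoxic and 35, 45, 45 and 47 hypoxic cells on lanes 1 to 4. A kept normoxic cell had a median of 1040650 gene reads (range 67512 to 1570753) and a kept hypoxic cell 1025720 (range 51842 to 2013844). Lane 1 was shallower, with medians of 273393 and 692223 reads, and lost the most wells, 9 normoxic and 13 hypoxic. Each condition is 1 sample without a replicate, so every comparison describes these 2 sets of cells and carries no test. No plate column held both conditions. An effect of plate side or library preparation therefore cannot be told apart from hypoxia in any comparison, that of gene reads with spike-in reads included. The median log2 ratio of hypoxia over normoxia over the 9127 measured genes was -0.29, and changes are to be read against that shift, which lies inside the range of the matched random lists.

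The 15 largest and 15 smallest ratios were taken among genes with a pooled CPM of 20 or more, reads in 20% or more of the cells of the higher condition and 1 direction in all lanes. Of the 15 largest, 5 belonged to genes on the fixed HIF target or hypoxia metagene lists (ADM, NDRG1, HK2, CA9 and TMEM45A). The others included 2 xenobiotic-metabolising enzymes. CYP1A1, a monooxygenase known as a target of the aryl hydrocarbon receptor, stood at 0.725 CPM in normoxia and 3934 CPM in hypoxia, a log2 ratio of 12.41 (95% counting interval 12.15 to 12.68, lanes 10.65 to 16.77, the last on 1 normoxic read, with a counting interval from 14.29 to 22.07). The normoxic sum of CYP1A1 held 1, 25, 72 and 22 reads on lanes 1 to 4. Its interval takes these reads as independent and is too narrow where they are copies of few molecules. CYP1B1, a relative of CYP1A1, stood at 272 and 10834 CPM (log2 ratio 5.32, interval 5.30 to 5.33). ADM, which encodes the vasodilator peptide adrenomedullin, was 245-fold higher in hypoxic cells. LOX, a collagen cross-linking oxidase, was 202-fold higher on 28 normoxic reads, a log2 ratio of 7.66 that was 6.89 with equal weight per cell and ran from 4.82 to 11.10 over lanes, the last on 1 normoxic read (interval 8.62 to 16.40). IGFBP3, an insulin-like growth factor binding protein, had a log2 ratio of 6.58. NDRG1 was 80.8-fold higher, HK2, the hexokinase of the first step of glycolysis, 64.3-fold, and CA9, a membrane carbonic anhydrase, 62.9-fold (log2 ratio 5.98). CA9 was at 7.84 on lane 3 and 4.09 on lane 4, and it had 0 normoxic reads on lanes 1 and 2, so its ratios there were at least 8.99 and 10.44 with a floor of 3 reads. PTPRN, EDN2, STRA6, HMOX1, FAM13A, TMEM45A and RGCC completed the 15 largest ratios, with log2 values from 4.83 (RGCC) to 6.02 (PTPRN). HMOX1 encodes haem oxygenase, which breaks down haem. KRT17 (log2 ratio 8.61) was found in too few cells for this ranking. Leaving out 1 lane moved 7 of the 15 by over 1.5-fold, with 0 sign changes. Without lane 4, CA9 was at 8.998, STRA6 at 7.86, FAM13A at 7.22 and LOX at 8.26. Without lane 3, CYP1A1 was at 13.44 and HMOX1 at 6.42, and without lane 2, EDN2 was at 6.87, HMOX1 at 4.86 and LOX at 6.9995. With thinned counts, EDN2 was at 6.91 (5.94 in the main analysis) and FAM13A at 5.91 (5.25).

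**Figure D1:**
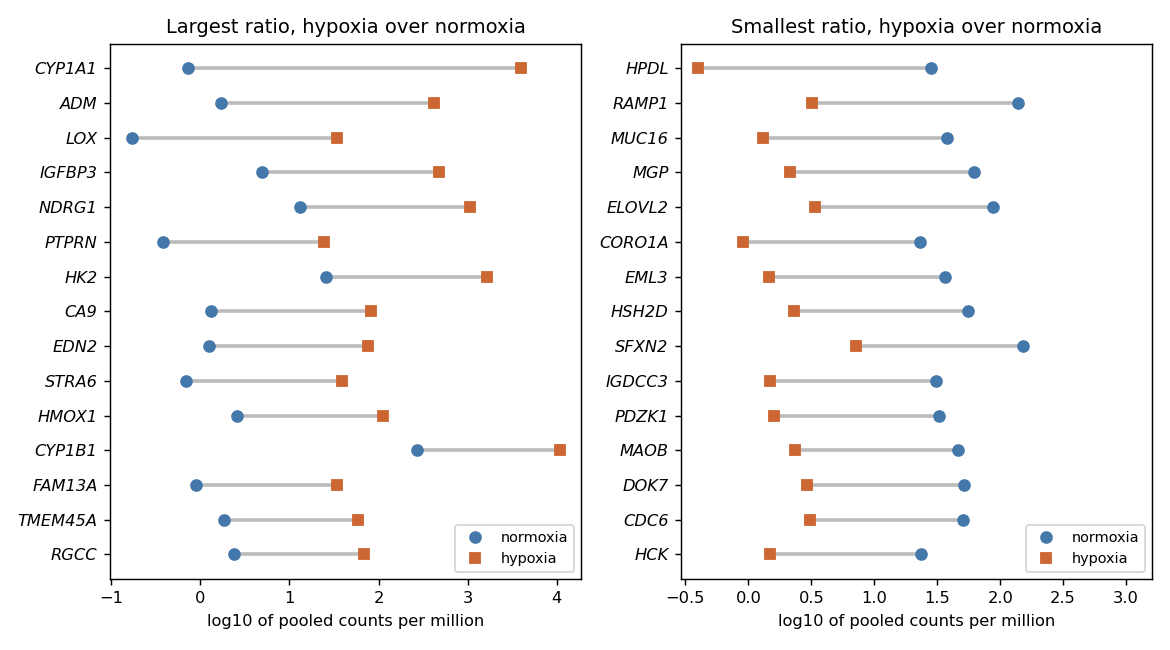
Pooled CPM (shown as log10) of the 15 genes with the largest and the 15 with the smallest ratio of hypoxia over normoxia, with normoxia as circles and hypoxia as squares. CYP1A1 spans the widest interval, from 0.725 to 3934 CPM, and HPDL the widest in the other direction, from 28.2 to 0.394.

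Within the same limits, the smallest ratios were those of HPDL (28.2 CPM in normoxia and 0.394 in hypoxia, log2 ratio -6.16, interval -6.53 to -5.81) and RAMP1, a receptor activity-modifying protein (137.5 and 3.19 CPM, log2 ratio -5.43). HPDL was at -5.10 on lane 1 and -4.59 on lane 4, and with 0 hypoxic reads on lanes 2 and 3 its ratios there were at most -9.07 and -8.74 with the same floor. With thinned counts it was at -8.04 on 1 hypoxic read (interval -13.34 to -5.55). MUC16, a mucin, was 29.2-fold lower in hypoxia, a log2 ratio of -4.87 that was -3.92 with equal weight per cell and -3.73 with thinned counts. It was at -4.24, -9.19 and -2.77 on lanes 2 to 4, and with 0 hypoxic reads on lane 1 at most -6.91 there. MGP, the matrix Gla protein, was 28.8-fold lower (log2 ratio -4.85, lanes -6.20 to -3.56, or -5.74 with thinned counts). ELOVL2, an elongase of polyunsaturated fatty acids, had a log2 ratio of -4.70, and CDC6, which loads the replicative helicase onto DNA, was 16.5-fold lower. CORO1A, EML3, HSH2D, SFXN2, IGDCC3, PDZK1, MAOB, DOK7 and HCK made up the rest of the 15, with log2 ratios from -4.67 (CORO1A) to -3.98 (HCK). KCNK5 (-10.50), below the CPM limit, was not ranked. Leaving out 1 lane moved 10 of the 15 by over 1.5-fold, with 0 sign changes. Without lane 4, HPDL was at -6.77, MUC16 at -5.87, IGDCC3 at -5.57, EML3 at -5.39 and HCK at -4.64. Without lane 3, MGP was at -5.79, PDZK1 at -5.47, MUC16 at -3.77, MAOB at -3.67 and IGDCC3 at -3.61. Without lane 2, HPDL was at -5.57, CORO1A at -5.51, MAOB at -4.97 and PDZK1 at -3.69, and without lane 1, HPDL was at -6.94 and HSH2D at -5.30.

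Known targets of hypoxia-inducible factor (HIF) outside glycolysis were higher almost as a whole. Of 30 measured members 29 were at least 1.5-fold higher in hypoxia, and the median log2 ratio was 3.29, above nearly all matched random lists (middle 95% from -0.68 to 0.07). Within the 4 lanes the median ran from 3.03 to 3.47. VEGFA, the vascular endothelial growth factor, was at 53.8 and 1243 CPM (log2 ratio 4.53), and BNIP3, a mitophagy receptor, at 107.6 and 1876 CPM (4.12). The exception was CA12, another carbonic anhydrase, at 377 and 128.6 CPM (log2 ratio -1.55). The hypoxia metagene list of 49 measured members was divided: 23 were higher and 16 lower (27 and 10 with TMM, 19 and 22 with spike-in scaling), with a median of 0.48, and that median turned to -0.22 when the sums were scaled to pooled spike-in reads. Its lower members included the tubulin gene TUBA1B (-2.75), the thioesterase gene ACOT7 (-2.38) and the mitotic kinesin gene KIF4A (-1.45), picked after their values were seen. TUBA1B shares reads with near-identical copies and is uncertain.

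The genes of the oxygen-sensing machinery did not move together. KDM3A, a histone demethylase, and EGLN3 and EGLN1, the prolyl hydroxylases that mark HIF for degradation, had log2 ratios of 3.80, 3.59 and 2.04. HIF1A itself was lower, at 208 and 115.1 CPM (log2 ratio -0.86), while EPAS1, which encodes HIF-2 alpha, was higher, at 14.4 and 83.6 CPM (2.53, or 3.13 with thinned counts). Over the 20 measured hydroxylases, demethylases and HIF subunits the median was 0.48, with 9 higher and 2 lower (11 and 0 with TMM, 7 and 5 with spike-in scaling), and it turned to -0.23 with spike-in scaling.

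Glycolytic genes were higher and genes of mitochondrial oxidation lower. Of 23 measured glycolysis genes 19 were higher and 0 lower by 1.5-fold (21 and 0 with TMM, 17 and 2 with spike-in scaling), with a median log2 ratio of 2.46 (lanes 2.24 to 2.68). PFKFB3 and PFKFB4, which make the activator of phosphofructokinase, had ratios of 4.28 (4.89 without lane 4) and 4.20, ENO2 4.03, the glucose transporter gene SLC2A1 3.32 and LDHA, which makes lactate, 2.46. The 4 members within 1.5-fold were HK1 (0.53), TPI1 (0.47), PFKL (-0.25) and PFKM (-0.38). GAPDH, PGK1, ALDOA and LDHA have pseudogene copies, so their values are uncertain. In the tricarboxylic acid cycle 14 of 19 genes were lower and 0 higher (10 lower and 1 higher with TMM). The median was -1.01 for the pooled lanes and ran from -0.85 to -0.55 within lanes. Pyruvate carboxylase PC (-2.01), FH (-1.56), IDH3A (-1.56) and citrate synthase CS (-1.42) led. Among nuclear genes of the respiratory chain 27 of 33 were lower and 0 higher (median -0.81), but with TMM 14 were lower (median -0.53). The lower members included ATP5MC1 (-1.78), ATP5F1A (-1.63), NDUFB10 (-1.52) and CYC1 (-1.36). The mitochondrial ribosome had 13 of 16 lower, or 6 lower and 1 higher with TMM, and its median of -0.72 (-0.44 with TMM) lay inside the random range (-0.80 to 0.18); MRPS7 was at -1.42.

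The 13 genes of the mitochondrial genome were also lower, with a median log2 ratio of -1.23 and 11 of them past 1.5-fold. MT-ATP8 (-3.46), MT-CYB (-3.11), MT-CO3 (-3.06) and MT-ATP6 (-2.53) had the smallest ratios. MT-ND4 (-0.24) and MT-ND6 (-0.04), named after their values were seen, were nearest to 0. The share of a cell's reads in these genes had a median of 2.42% in normoxic and 0.65% in hypoxic cells. Nuclear copies of mitochondrial genes can share these reads.

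Genes of the cell cycle were lower in hypoxia. Of 29 measured G1/S genes 28 were lower, with a median log2 ratio of -2.44 (lanes -3.04 to -2.03). CDCA7 (-4.76), CDC6 (-4.04), CDC45 (-3.95) and HELLS (-3.83, or -4.47 without lane 2) had the smallest ratios, and SLBP (-0.23) was the member within 1.5-fold. Of 36 G2/M genes 32 were lower and 0 higher (27 lower and 1 higher with TMM), with a median of -1.10. That median varied between lanes from -2.38 to -0.11, and 22 of the 36 members kept 1 direction in all 4 lanes. UBE2C, named after its value was seen, had a positive ratio (0.55, or -0.15 with spike-in scaling). BIRC5, an inhibitor of apoptosis expressed in mitosis, was at -2.10, the proliferation marker MKI67 at -1.91 (115.4 and 30.7 CPM), AURKB at -1.72 and TACC3 at -1.68.

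Targets of the oestrogen receptor were mostly lower. Of 24 measured members 16 were lower and 3 higher, with a median log2 ratio of -1.72 (lanes -1.92 to -1.52). With a strict gene filter the median was -0.74. ESR1, the receptor gene, stood at 176.9 and 33.4 CPM (log2 ratio -2.40), PGR, the progesterone receptor gene, at 32.5 and 5.68 (-2.52), and GREB1 at 374 and 105.3 (-1.83). ELOVL2 (-4.70), PDZK1 (-4.34) and RAPGEFL1 (-3.78, or -5.14 with thinned counts on 3 hypoxic reads, interval -7.44 to -3.56) had smaller ratios still. KCNK5, a potassium channel gene, had 2 reads in all hypoxic cells and a log2 ratio of -10.50 with a counting interval from -13.55 to -8.65. Both reads lay on lane 2, so without that lane the ratio was at most -9.43. It was -9.87 without lane 3 (interval -12.92 to -8.01) and -7.43 with thinned counts on 1 hypoxic read (-12.74 to -4.93). TFF1, a classical target, was at 1344 and 1432 CPM (0.09), with a lane range from -1.02 to 1.34. AREG (2.07), picked after its value was seen, was higher. Markers of luminal epithelium had 5 of 20 genes higher and 6 lower (7 and 4 with TMM, 1 and 13 with spike-in scaling; median -0.21, near the median of all genes): ELF3 was at 2.56, SPDEF at -1.54, XBP1 at -1.41 and GATA3, a luminal transcription factor, at -1.27. The sign of that median depended on the scaling, at 0.07 with TMM.

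All 19 measured genes of cholesterol synthesis were lower, with a median log2 ratio of -1.87 (lanes -2.12 to -1.53). LSS was at -2.77, MVK at -2.67, FDPS at -2.45 and FDFT1 at -2.34. In fatty acid synthesis and lipid storage 10 of 13 genes were lower and 2 higher (median -1.23). The elongase ELOVL6 (-3.18) and the desaturase FADS1 (-3.07) were lower. The lipid droplet genes HILPDA (3.54) and PLIN2 (3.41, or 2.41 without lane 1) were higher.

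Stress genes lay on both sides. In the unfolded protein and ATF4 list 13 of 22 genes were higher and 5 lower (15 and 4 with TMM, 9 and 6 with spike-in scaling; median 1.08, lanes 0.89 to 1.14). Higher members were the cystine transporter gene SLC7A11 (3.58, or 2.74 with thinned counts), DDIT3, which encodes CHOP (3.04), and VLDLR (2.42), with TRIB3 (2.19) and ASNS (1.56) as further ATF4 targets picked after their values were seen. SDF2L1 was at -2.88 and, picked likewise, HYOU1 was at -1.03, PDIA4 at -1.005, CALR at -0.49, HSPA5 at 0.31 and DNAJB9 at 0.51 (-0.39 and -0.19 with pooled spike-in scaling). Of 19 p53 targets 8 were higher and 2 lower (13 and 1 with TMM, 4 and 5 with spike-in scaling; median 0.51, 1.28 with the strict gene filter and -0.20 with spike-in scaling), among them GDF15 (3.53), BBC3 (3.11), the cell cycle inhibitor gene CDKN1A (1.95) and MDM2 (1.37). Cytosolic heat shock genes had 4 of 12 higher and 4 lower (4 and 2 with TMM, 2 and 8 with spike-in scaling; median -0.22, 0.06 with TMM), with DNAJB1 at 1.30 and BAG3 at -1.47; HSPA1A (1.29) and HSPA1B (1.30) are near-identical copies and uncertain. Immediate early genes were split 4 higher and 5 lower of 16 (6 and 3 with TMM, 3 and 9 with spike-in scaling; median 0.00, or -0.70 with spike-in scaling), with NR4A1 at -2.62, EGR2 at -2.46, FOSB at -2.26 and ATF3 at 2.11.

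Genes of matrix and migration were higher in part. Of 11 measured genes of the mesenchymal list 7 were higher and 2 lower (median 2.51, lanes 2.16 to 2.89, or 0.80 with no gene filter). TGFBI (4.10), the integrin gene ITGA5 (3.96), LOXL2 (3.91, or 5.28 without lane 4) and LOX (7.66) led, while TGFB1 (-2.37) and fibronectin FN1 (-1.73), named after their values were seen, were lower. Of 12 genes from the breast cancer stem cell list 8 were higher and 1 lower (median 1.42; 10 and 1 with TMM, 7 and 2 with spike-in scaling): the Notch ligand gene JAG1 was at 4.08, CXCR4 at 3.18, ALDH1A3 at 3.03 (4.42 without lane 4, 3.75 with thinned counts) and SOX9 at 2.48. Collagen hydroxylation and matrix genes had 6 of 12 higher and 2 lower (6 and 1 with TMM, 5 and 5 with spike-in scaling; median 0.70, 1.71 with the strict gene filter, -0.0072 with pooled spike-in scaling and 0.19 with spike-in scaling by cell medians), with the prolyl 4-hydroxylase genes P4HA1 at 3.57 and P4HA2 at 2.40. In the autophagy list 6 of 14 were higher and 3 lower, or 6 and 0 with TMM and 3 and 6 with spike-in scaling (median 0.27, or -0.44 with spike-in scaling), with BNIP3L at 2.74, SQSTM1 at 1.64 and OPTN at 1.21.

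The lists of pH regulation, apoptosis, interferon response, the cytosolic ribosome and housekeeping did not stand apart from matched random lists. The pH regulation list had a median of -0.30 (2 higher and 3 lower of 10, 3 and 3 with TMM, 2 and 7 with spike-in scaling, CA2 at -1.41 and SLC9A1 at 1.57). Apoptosis regulators had 0.22, or -0.49 with spike-in scaling (3 higher and 3 lower of 13, 5 and 2 with TMM, 2 and 5 with spike-in scaling, TNFRSF10B at 1.35, BID at -1.07 and BAK1 at -0.88). Interferon response genes had 0.03, or -0.67 with spike-in scaling (6 higher and 7 lower of 17, 6 and 6 with TMM, 3 and 9 with spike-in scaling). In that list HLA-B (2.28) and HLA-C (1.98), which share reads with related HLA genes, were higher and OAS3 (-1.44, or -2.75 without lane 3) was lower. The cytosolic ribosome had a median of -0.0082 (0.27 with TMM), at percentile 97.42 and just inside the upper bound of the random range (-0.0067). Of its 46 genes 41 were within 1.5-fold, 2 higher and 3 lower (11 and 0 with TMM, 0 and 27 with spike-in scaling). Housekeeping controls had 0.02 (-0.68 with spike-in scaling), with 4 of 13 higher and 5 lower (5 and 5 with TMM, 1 and 7 with spike-in scaling), although the haem synthesis gene HMBS was at -2.25 and UBC, a ubiquitin gene with related copies, at 2.06. Markers of other cell types were scarce: 1 of 10 fibroblast markers was measured (COL1A1, 12.9 and 22.8 CPM, a log2 ratio of 0.82 that was -0.35 without lane 1), and 0 of 11 leukocyte and 0 of 7 endothelial markers were. Of 10 basal markers 2 were measured, KRT17 (0.115 and 44.7 CPM, log2 ratio 8.61, 10.41 without lane 3 and 7.94 without lane 4) and EGFR (4.83 and 35.7 CPM, 2.89, or 3.72 without lane 3). Their median of 5.75 lay above nearly all matched random pairs (middle 95% from -1.72 to 1.56), but was -0.046 with no gene filter. No row matched the list of nuclear long non-coding RNAs.

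**Figure D2:**
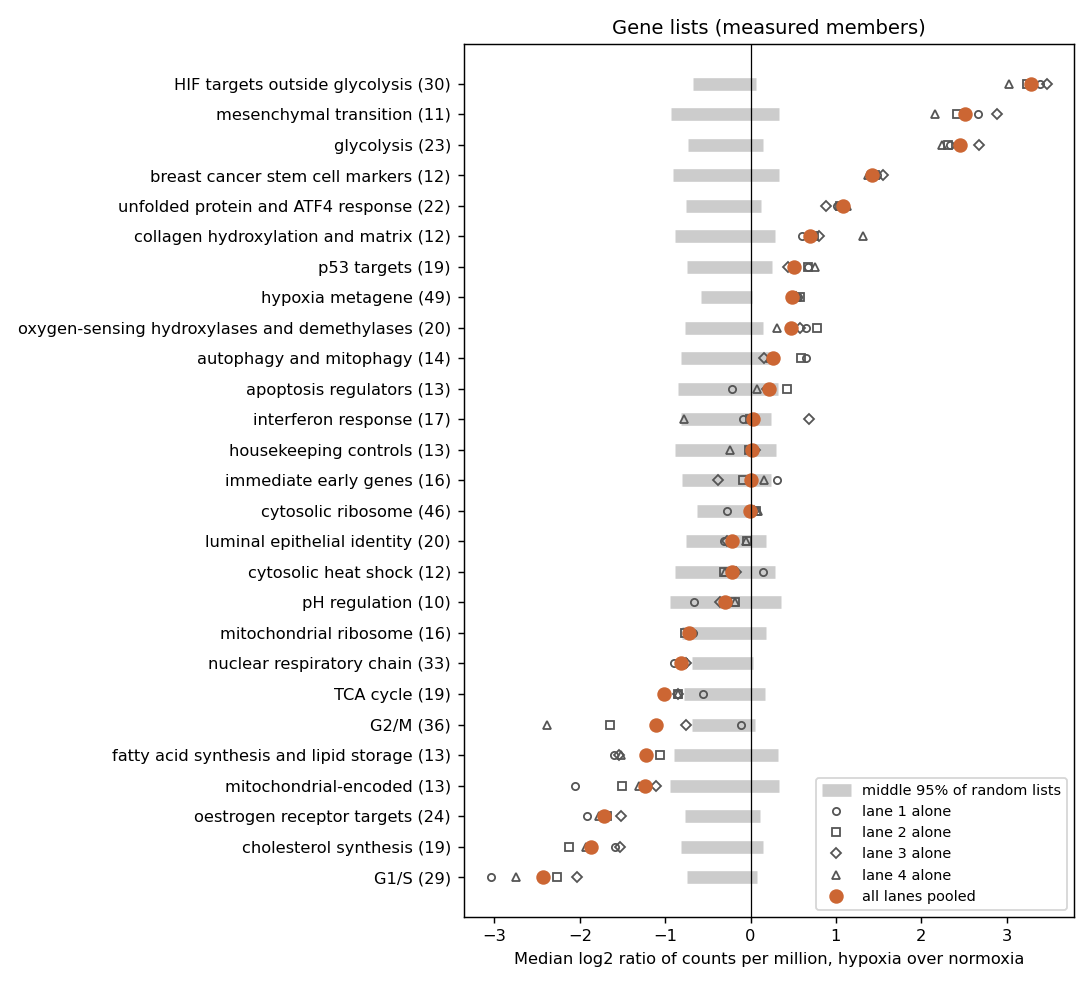
Median log2 ratio of hypoxia over normoxia for each gene list with 5 or more measured members (number in brackets), for all lanes pooled (filled circles) and for each lane alone (open symbols), with the middle 95% of matched random lists as grey bars. HIF targets lie at 3.29 and G1/S genes at -2.44, and the 4 lanes of the G2/M list spread from -2.38 to -0.11.

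At an equal depth of 50000 reads, several genes differed widely between the conditions in the share of cells with reads. NDRG1 reads were found in 22.03% of normoxic cells (interval 16.2% to 28.9%) and 100% of hypoxic cells (97.9% to 100%). CA9 was found in 2.26% (0.619% to 5.68%) and 52.9% (45.2% to 60.5%), where the normoxic share was 0.763% without lane 4 and 1.19% with the strict cell filter. CYP1A1 was found in 1.13% (0.137% to 4.02%) and 66.9% (59.3% to 73.8%). Without thinning these shares were 2.26% and 58.1% for CA9, 3.39% and 71.5% for CYP1A1, and 41.8% and 100% for NDRG1. In the other direction, PYCR3, a proline synthesis gene, was found in 96.6% and 21.5% of cells, the thiosulfate sulfurtransferase gene TST in 86.4% and 12.8%, SFXN2 in 84.2% and 12.8%, SLC27A4 in 83.1% and 12.2%, and IFITM2 in 98.9% and 30.2%. ELOVL2, MFSD3, CTPS1 and AK1 were the others of the 10 largest differences. The blank well held 0 reads of CA9 and of CYP1A1, but its gene reads were too few to show a background of these genes.

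Cell by cell, HIF targets and glycolysis genes separated the conditions almost fully, while the G1/S, G2/M, oestrogen receptor and mitochondrial-encoded scores overlapped more. HIF targets took a median of 0.156% of reads in normoxic and 1.65% in hypoxic cells. Of the normoxic cells 1 (0.565%, interval 0.0143% to 3.11%) reached the 10th percentile of hypoxic cells, and 0 hypoxic cells lay at or below the normoxic 90th percentile, which allows up to 2.12% (1.16% with the mean of member log2 values as the score). Glycolysis genes took 2.58% and 11.5% of reads, with 0 normoxic cells at the hypoxic 10th percentile and 1 hypoxic cell (0.581%) at or below the normoxic 90th. The hypoxia metagene, whose sum is carried by its abundant glycolytic members, took 2.85% and 11.3%. The G1/S score had medians of 0.376% and 0.066%, with 98.3% of hypoxic cells (interval 94.99% to 99.6%) at or below the normoxic median. The G2/M score had medians of 0.190% and 0.014%, yet 11 hypoxic cells (6.40%, interval 3.24% to 11.2%) lay at or above the normoxic 90th percentile, and its coefficient of variation was 1.19 in normoxia and 2.88 in hypoxia. The oestrogen receptor target score had medians of 0.606% and 0.389% and coefficients of variation of 0.44 and 0.88, and 21 hypoxic cells lay at or above the normoxic 90th percentile. That sum is carried in large part by abundant members that were not 1.5-fold lower, such as TFF1 (0.09), SLC7A5 (1.88) and CCND1 (-0.12). A high score can therefore come from a few such genes while other targets are low. The mitochondrial-encoded score had medians of 2.42% and 0.66%.

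**Figure D3:**
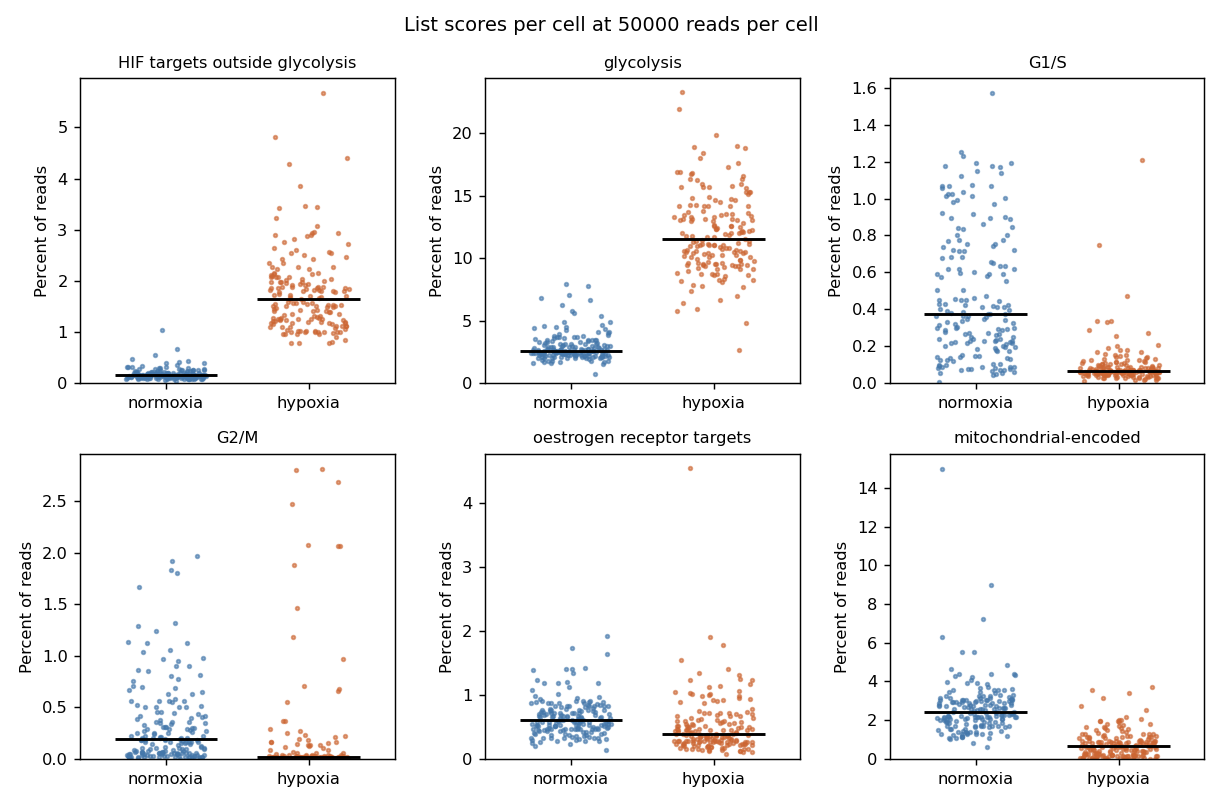
Percent of each cell's reads in the genes of 6 lists after thinning to 50000 reads, for the kept normoxic and hypoxic cells, 1 point per cell, with the median as a line. HIF target scores barely overlap, with medians of 0.156% and 1.65%, whereas 11 hypoxic cells reach the upper range of normoxic G2/M scores.

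Of the 10 genes that varied most between cells in each condition, 1, KRT81, was common to both. In normoxia they were IFI27, KRT81, ABCC3, UTRN, BCAS1, IFI6, CAV1, DDIT3, MUC5B and NCKAP5, and IFI27, an interferon-induced gene with reads in 10.2% of thinned cells, had a variance to mean ratio 99.03 times the trend. Most normoxic IFI27 reads before thinning lay on lane 4 (4615, against 23 to 326 on each other lane). The same held for KRT81 (2950 against 91 to 626), ABCC3 (4177 against 205 to 433) and IFI6 (8140 against 695 to 1752). The others of the 10 were less concentrated on that lane. In hypoxia they were KRT86, KRT81, PLIN2, COTL1, IGFBP3, HSPA6, PLK1, LOX, CEACAM6 and OAS1. Some of these were also concentrated on 1 lane by their hypoxic reads before thinning. KRT86 had 6317 on lane 4 (853 to 1712 on each other lane) and PLIN2 15294 on lane 1 (2370 to 5866). CEACAM6 had 8871 on lane 2 (553 to 2282) and OAS1 2456 on lane 3 (at most 468). The other hypoxic genes of the 10 were less concentrated on any 1 lane. KRT86 and KRT81, hair-type keratins that share reads, lay 42.7 and 38.3 times over the trend, and PLK1, a mitotic kinase found in 12.8% of hypoxic cells, 25.1 times.

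Clustering within each condition gave 6 clusters of normoxic cells (15 to 37 cells) and 5 of hypoxic cells (21 to 45 cells), and each cluster held cells of all 4 lanes. A cycling (G2/M)-like cluster appeared in both, with 37 normoxic cells (20.9%) and 21 hypoxic cells (12.2%). These clusters were not alike, and their sizes are not to be compared. TOP2A was among the 10 leading genes of both. In the normoxic cluster it was 3.72-fold higher than in the other cells, of which 77.9% also had TOP2A reads. In the hypoxic cluster it was 85.4-fold higher, and 12.6% of the other cells had TOP2A reads. The other clusters did not meet the marker rule and stayed unnamed. Hypoxic cluster 1, of 45 cells, had a median mitochondrial-encoded share of 0.158%, against medians from 0.542% to 1.06% in the other 4 clusters. That cluster also had the fewest genes per cell of the 5 (median 7018, against 7076.5 in cluster 4). Its spike-in share of reads was the highest (median 0.153%, against 0.144% in cluster 2), as were its gene reads (median 1148540). The number of clusters depended on the settings. Other resolutions gave 3 or 8 in normoxia and 3 or 9 in hypoxia. At the same resolution, another seed, 1000 variable genes or the removal of cell cycle genes gave 7 hypoxic clusters and 4000 variable genes gave 6, so none of these gave 5 again, and the adjusted Rand index against the 5 clusters was as low as 0.519 (1000 variable genes).

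Hypoxic cells gave fewer genes and fewer gene reads per spike-in read. At equal depth a median of 6594 genes was found per normoxic and 5741 per hypoxic cell (8991 and 7718.5 without thinning). Gene reads per spike-in read had medians with a ratio of hypoxia over normoxia of 0.702, from 0.634 to 0.788 within lanes. The ratio from pooled sums, used for spike-in scaling unless cell medians are named, was 0.614. The 2 ratios shift every log2 value by -0.51 and -0.70, and with the smaller shift the median was -0.027 for the hypoxia metagene, -0.033 for oxygen-sensing genes, -0.0052 for p53 targets and -0.25 for autophagy genes.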

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

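The blank well, which entered no comparison, held 13467 spike-in reads and had 1.06% of its reads in genes, above the 0.022% (3 counts) that a true 0 allows. Its gene reads came to 0.0140% of those of the median kept well. The gene with the most reads was DOT1L with 19, and HIF target and glycolysis genes held 12 reads (8.33%, interval 4.38% to 14.1%), between the pooled shares of 3.04% in normoxic and 14.01% in hypoxic cells.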

How the results depend on the processing

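Scaling to spike-ins, by pooled sums or cell medians, and the comparisons that use it, were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the labels name no replicate cultures and no result came from a test. A sign change was called only where the main value lay further from 0 than the SD over lanes. Over 28 list medians and the median of all measured genes, 71.5% of the values under an alternative moved by less than the SD over lanes, 25.2% moved by more with no called sign change and 3.25% had a called sign change; over the named genes these shares were 87.2%, 12.4% and 0.426%. The exclusion of very deep wells removed 0 wells and so tested nothing, yet its values count in these shares as moved by less than the SD. Values without 1 lane were judged against the SD over the same lanes, which a single lane can widen. IFI27 went from -1.23 to 1.82 without lane 4 and still counted as moved by less than the SD (3.72). For both reasons these shares overstate how stable the results were. The medians of HIF targets, glycolysis, G1/S, G2/M, oestrogen receptor targets, cholesterol synthesis and mitochondrial-encoded genes kept their direction under every alternative run.

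TMM moved the median of all measured genes to -0.0074, median-of-ratios scaling to -0.021 and spike-in scaling to -0.99. The hypoxia metagene median was 0.76 with TMM, 0.75 with median of ratios, 0.72 without the top 50 genes in the totals, 0.46 without mitochondrial-encoded genes in the totals, 0.43 with equal weight per cell, 0.43 with thinned counts, 0.85 with the strict gene filter and -0.22 with spike-in scaling. With TMM, median of ratios, totals without the top 50 genes and spike-in scaling, HIF targets had medians of 3.57, 3.56, 3.53 and 2.59, glycolysis genes 2.74, 2.72, 2.69 and 1.75, and oestrogen receptor targets -1.44, -1.45, -1.48 and -2.42. With spike-in scaling by cell medians the medians were 2.78 for HIF targets, 1.94 for glycolysis, -2.23 for oestrogen receptor targets, -2.95 for G1/S, -2.38 for cholesterol synthesis, -1.75 for mitochondrial-encoded genes and -0.027 for the hypoxia metagene. The oestrogen receptor target median was -0.74 with the strict gene filter, which removes members of low level. Cholesterol synthesis was at -1.59 with TMM and -2.57 with spike-in scaling, G1/S at -3.14 and mitochondrial-encoded genes at -1.94 with spike-in scaling. Leaving out each lane gave -1.75 to -1.21 for mitochondrial-encoded genes, 0.46 to 0.53 for the hypoxia metagene and -1.43 to -0.92 for G2/M.

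Called sign changes came from the scaling in all but 1 case. With TMM, median of ratios and totals without the top 50 genes, the luminal median was 0.068, 0.055 and 0.026, the cytosolic heat shock median 0.060, 0.047 and 0.019, MT-ND4 0.042, 0.029 and 0.00088, and SLBP 0.052, 0.039 and 0.011. PFKL was 0.035 with TMM and 0.022 with median of ratios. With spike-in scaling the medians of p53 targets (-0.20), collagen and matrix genes (-0.0072), oxygen-sensing hydroxylases (-0.23) and autophagy genes (-0.44) turned, as did HK1 (-0.17), TPI1 (-0.23) and DNAJB9 (-0.19). By cell medians, p53 targets (-0.0052), oxygen-sensing hydroxylases (-0.033), autophagy genes (-0.25) and TPI1 (-0.041) turned, while the collagen and matrix median (0.19) did not. The basal marker median was -0.046 with no gene filter, which adds members of few reads. Another 5.28% of list values and 1.38% of gene values changed sign from a main value within the SD over lanes of 0, and were left uncalled. With spike-in scaling by pooled sums and by cell medians these included the medians of apoptosis regulators (-0.49 and -0.30), interferon response (-0.67 and -0.48), immediate early genes (-0.70 and -0.51) and housekeeping controls (-0.68 and -0.49), and HSPA5 (-0.39 and -0.20) and TFF1 (-0.61 and -0.42). With TMM, the cytosolic ribosome median was 0.27, MT-ND6 0.24 and NQO1 0.15. Uncalled changes also came from other alternatives, such as COL1A1 at -0.35 without lane 1. The shifts from scaling follow from the construction of each scaling, 1 factor for all genes.

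The share of cells with 5 or more CA9 reads was 0.565% in normoxia and 26.2% in hypoxia. The share of normoxic cells at or above the hypoxic 10th percentile of the HIF target score was 0 with unthinned counts, the strict cell filter and thinning seed 2, and 0 to 0.769 percent when each lane was left out. The share of hypoxic cells at or below the normoxic 90th percentile of that score was 1.16% with the mean of member log2 values and 0 under every other alternative. At resolution 0.5 there were 3 clusters in each condition, and at resolution 1.5 there were 9 in hypoxia; the cause was not tested. Depth limits genes with few reads within a lane, where a ratio on 0 reads is a bound. On lane 1, CA9, EDN2, KRT17 and STRA6 had 0 normoxic reads, as CA9 had on lane 2, and KCNK5 had 0 hypoxic reads on every lane but lane 2.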

Other observations

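The tests of list genes of the aryl hydrocarbon receptor, of TMM scaling, of mitochondrial shares in deeper cells, of shared mitochondrial transcripts, of plate columns, of the share of cells with CYP1A1 and of HIF target scores were chosen after the results had been seen. All patterns below come from these data and were tested on them.

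The hypoxic cells included a small set of cells with strong mitotic expression. At equal depth the 18 hypoxic cells with the most G2/M reads held 83.4% of all G2/M reads of the hypoxic cells, against 39.1% in the top 18 normoxic cells. For G1/S the same shares were 35.95% and 24.5%. The hypoxic G2/M score reached 2.81% of reads, above the normoxic maximum of 1.97%.

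Mitochondrial-encoded genes were lower in hypoxic cells by unequal amounts. The strict cell filter, planned as a test of shallow or failing wells, left the list median at -1.22 and moved it by less than the SD over lanes, so it decides nothing. Failing wells stay open for part of the shift, since hypoxic cluster 1, with the lowest mitochondrial share, had the fewest genes and the highest spike-in share. The margins were small, with 7018 genes against 7076.5 in cluster 4 and a spike-in share of 0.153% against 0.144% in cluster 2. Cluster 1 also had the highest median gene reads of the hypoxic clusters (1148540). Failing wells are argued against as the whole source by hypoxic cluster 5. Its median mitochondrial share was 1.06%, against 2.05% to 2.74% in the normoxic clusters. Its genes (8810) and spike-in share (0.083%) lay within the medians of the normoxic clusters (8423 to 9592 genes, 0.066% to 0.111%). Shallow wells are argued against by the kept cells at or above the median depth, in which the log2 ratio of the median mitochondrial shares was -1.99 with an SD over lanes of 0.27. A larger part of the reads taken by other genes does not account for the whole shift, since the median with TMM scaling was -0.95 with an SD over lanes of 0.41. The inequality between genes may in part come from how reads are counted: MT-ATP8 and MT-ATP6, which share 1 transcript, differed by 0.934 in log2 ratio, and MT-ND4L and MT-ND4 by 0.989, and a lower amount of mitochondrial RNA under hypoxia also stays open. Hypoxia cannot be told apart here from an effect of plate side or library preparation.

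CYP1A1 and CYP1B1 were higher in hypoxic cells. Their presence in a few wells alone is argued against, since 66.9% of hypoxic cells had CYP1A1 reads at equal depth (interval 59.3% to 73.8%), but the top 18 cells held 64.7% of the reads, so how far a few wells set the size of the ratio stays open. These 2 parts were separated only after the second share, the one test planned for a few wells, had left the question open. A candidate explanation is aryl hydrocarbon receptor activity: 6 of 7 other measured targets were higher, with a median log2 ratio of 1.89 at percentile 99.96 of matched random lists. The list held 11 targets. Those below the gene filter were left out: CYP1A2 (log2 ratio -3.98), ALDH3A1 (3.23), UGT1A6 (2.09) and EREG (1.36). AHRR (1.61 CPM in normoxia and 20.7 in hypoxia) and ALDH1A3 (1.91 and 15.6) passed that filter by their hypoxic level alone. These 2 could therefore enter only as higher, so the filter favoured higher ratios. AHRR was at 3.69 (4.42 without lane 4), TIPARP at 2.07 and NFE2L2 at 1.89, while NQO1 was at -0.13, and ABCG2, ALDH1A3 and SLC7A5 also stand on other lists, so the list is not specific. An effect of the plate side or of library preparation cannot be told apart from hypoxia, here as in every comparison, because 0 plate columns held both conditions.

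Some hypoxic cells had G2/M scores as high as the highest normoxic cells. Wells whose cells lacked a hypoxia response are argued against as the source of all these cells, since 0 hypoxic cells had a HIF target score at or below the normoxic 90th percentile. With the mean of member log2 values as the score 1.16% of hypoxic cells did, fewer than the 6.40% with high G2/M scores. The 11 cells with high G2/M scores had HIF target scores from 0.788% to 3.23% of reads, against a normoxic 90th percentile of 0.286%. Their glycolysis scores ran from 9.61% to 16.9%, above the normoxic maximum of 7.94%. These values argue against such wells for each of the 11 cells. A single lane is argued against, since the lane with the most held 45.5% of the 11 cells. Cells that went on dividing under hypoxia remain a hypothesis, and wells with 2 cells were not tested.

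Lane 1 differed from the other lanes in depth, with 21114046 normoxic reads against 44396228 to 53265376 in the others.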
